A study of Drosophila melanogaster with 12 samples.

How the data were processed

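The material was a defined mixture of fly sequences, not RNA from flies. Per the labels, PCR products of 5725 cDNA clones from the Drosophila Gene Collection, held in 28 pools, were combined at set relative amounts into a mixture called A and a mixture called B. Each mixture was transcribed in vitro and labelled with Cy3 or Cy5, and A in one dye was hybridised with B in the other dye to 2-colour Agilent expression arrays. Per the labels, the steps from transcription onward were repeated; the group names hold 2 rounds, called preparations here. Each preparation has both dye orientations, and each orientation has 3 arrays, which gives 4 groups and 12 arrays. The groups are named as in the labels: A1Cy3_B1Cy5 and A1Cy5_B1Cy3 for preparation 1, and A2Cy3_B2Cy5 and A2Cy5_B2Cy3 for preparation 2.

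The authors deposited scanner output for each array, made with Feature Extraction 9.5.3.1 per the file headers. The intensity columns used here, mean spot brightness and median local background per channel, are linear and not normalised per the file headers. A further pair of deposited intensity columns holds signals that the software had background-subtracted and dye-normalised, per the file headers; these entered as an alternative. The well-above-background, saturation and outlier flags are also the software's, per the file headers. The deposited table of nominal values was read as the unit other, because it holds numbers and text codes. It lists a ratio of A over B for 8107 of the 32162 gene probes: 5278 at 1 and 2829 in 10 classes from 0.25 to 3.5. It lists 23310 probes at 0, which the labels do not explain either, and it holds text codes, MC for 725 probes, MF for 16 and NS for 4, also unexplained; these were tested but belong to no nominal class. How the authors assigned probes to clones is not given in the sources used here.

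Each array carries 45020 spots, of which 43603 are gene spots and 153 are negative controls. Background was corrected with normexp at an offset of 50, fitted on all spots, and each array was normalised by loess with control spots and outlier-flagged spots at weight 0. Outlier-flagged spots were left out and the spots of a probe were averaged; 9841 probes had more than 1 spot. Saturated spots were kept (9 combinations of probe and array). Every log2 ratio was turned to A over B from the dyes in the labels. A probe was tested if it was well above background in either channel on at least 6 of the 12 arrays, which left 10685 probes. Different probes of a gene were kept apart; the probe with the brightest mean intensity stands for a gene in the gene lists.

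The 3 arrays of a group share the labelled material, and the 2 groups of a preparation are separate labellings within 1 round, so the arrays of a preparation are technical replicates. Ratios were averaged over the 3 arrays of a group, then over the 2 dye orientations of a preparation, which cancels a dye effect that is alike in both. The p-values for A against B therefore rest on n = 2 preparations. They measure the spread from transcription to scanning, and the labels describe the repetition as starting from transcription. That there were 2 rounds in all is read from the group names, and whether the mixtures were also made again for each round is not stated. An intercept was fitted to the preparation values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment at 0.05; the moderated spread borrowed 2.71 prior degrees of freedom from all tested probes. The dye effect was tested in the same way on the difference between orientations, divided by 2. The difference between preparations can only be tested on the 12 arrays, with the dye as a covariate, so its p-values rest on technical spread. Shares carry exact binomial intervals at 95%, which cover counting error over probes only. The slope of measured on nominal log2 ratio was fitted per array over tested mixture probes; slopes of 6 arrays were compared with 6 by an exact permutation test over 924 arrangements. Neighbouring nominal classes were compared by permutation tests with 100000 resamples across probes, and probes are not independent replicates.

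Genes were named by a rule fixed before the data were examined: in each class other than 1 the 2 brightest called genes, the 5 largest departures from the nominal value, the 5 largest ratios among called probes of nominal ratio 1, the 3 brightest probes listed at 0, and the 5 largest dye effects among called mixture probes. In every part CG and clone names counted only where too few other symbols were left. The last part named none. All 8 gene lists were patterns on gene symbols, fixed at the same time. Symbols in the files are those of the array design; 18839 of 32162 probes were given a current symbol through locus tags or accessions in the RefSeq table of the Release 6 assembly, and the others keep the name in the files, so a gene can stand under an old and a current name. Coordinates are those in the files, on the build the headers name (dm3, BDGP release 5). Exon and UTR positions were not analysed here.

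The arrays with the same number share a slide, per the file headers; each slide holds 1 array of each group. Deviations of same-numbered arrays from their group means correlated with r from -0.49 to 0.42 over tested probes, with no common sign in the direction of A over B. In the direction of Cy5 over Cy3 the same r ran from 0.02 to 0.42 on slide 1 and from -0.09 to 0.49 on slide 2. On slide 3 it ran from -0.06 to 0.12. Some pairs of arrays on slides 1 and 2 thus shared part of their dye deviation, and those on slide 3 shared little. The slide was fitted as a block, as fixed beforehand, in the direction of A over B, so the block does not take up this shared dye deviation. A slide effect in the dye direction was added after seeing the data. Counts of calls with the block and from each slide alone are given beside the others. The slopes were also permuted within slides (216 arrangements), which was added after seeing the data. Per the file headers all arrays were scanned on the same day.

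The scripts were tested on simulated data for 10685 probes, drawn with the fitted spread. With the mixture's own classes and 2 preparations, the test of A against B recovered 63.5% of probes changed 1.2-fold, 98.4% of those changed 1.5-fold and 99.1% or more of those with larger changes, and it called 1.54% of unchanged probes. The 12 arrays taken as if independent called 14.8% of them. With 200 changed probes only, 50 per fold size, it recovered 0% at 1.2-fold, 50% at 1.5-fold, 94% at 2-fold and 100% at 3-fold. For the dye effect with 200 changed probes, recovery was 0%, 6%, 68% and 96% at the same sizes. For the preparation difference it was 60%, 92%, 100% and 100%, but this simulation held the spread between arrays only. It left out the spread between preparations and between labellings, so these shares cannot be set beside the others. The simulations of A against B gave each changed probe its full ratio at any brightness, so their shares do not measure recovery in these data. Among real tested probes 26.0% at 0.833, 84.3% at 0.667 and 91.1% at 1.5 were called in the set direction. Of the tested probes set at 1, 4.72% were called.

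Alternatives fixed beforehand were other background corrections, other normalisations, other filters on dim probes, other units of replication, an intensity trend, a test against a fold of 1.1, the slide as a block, 1 value per gene and each array left out in turn. Analyses of single slides and a slide effect in the dye direction were added after seeing the data. The number of arrays limits the precision.

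Explanations of patterns were tested against written bounds. Those for unusual binding, for another clone ratio and for the raised array and brightness in the class order were written after the result was seen. For the array with raised signal, 3 further explanations were tested and argued against: raised local background (61 in Cy5, others at most 62), the shared slide (at most 12191 probes above background on its other arrays) and binding alike at any probe (negative controls rose 0.199 times as far as probes listed at 0). RNA from fly cells was added to the explanations after these results and before its own value. The splits of arrays were drawn with a seed that was changed once and then set back to the first; the other draw did not contain the split with the highest count. Figures were drawn with matplotlib 3.10.9.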

Results

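The series measured 2 mixtures of in vitro transcribed fly cDNA clones against each other on 12 dual-channel arrays, so that the true ratio of each clone between mixture A and mixture B was set by the experimenters. In 11 arrays, between 10534 and 12191 of the 32162 gene probes were well above background in either channel, and 1 array, A1Cy5_B1Cy3 replicate 2, had 29088. Between 87.9% and 89.9% of probes with a nominal ratio were above background in those 11 arrays, and 98.4% in the other one. Median mixture signal ran from 6711 to 9943 in Cy3 and from 7955 to 13173 in Cy5 over those 11 arrays, and was 7079 and 8489 in the other.

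The first question was which probes the arrays separate between A and B. Among the brightest probes set at 0.25, Hph, the prolyl hydroxylase of the hypoxia response, measured -2.13 ± 0.05 (log2 A over B, SD of 2 preparations, as below), and poe, a ubiquitin-ligase family protein, measured -2.04 and -1.96 in the 2 preparations. At the other end, Syx16, a SNARE protein, measured 1.66 ± 0.12 and PGRP-SC1b, a peptidoglycan-cleaving enzyme of the gut, 1.52 ± 0.13, both set at 3.5. In total 1867 probes were called higher in A and 1351 lower in A, of 10685 tested. Of the 2829 probes set at a ratio other than 1, 2344 (82.9%, interval 81.4 to 84.2) were called in the set direction and 17 (0.601%) against it; 193 of the 2829 were too dim to test. Of the 5278 probes set at 1, 216 (4.09%, interval 3.57 to 4.66) were called. The calls included 626 probes set at 1 or listed at 0, which is 19.5% of all calls (interval 18.1 to 20.9). These last 2 shares depended on the processing: they were 7.77% and 30.3% with normexp at offset 0, 6.76% and 33.8% with scanner-processed signals, 10.9% and 37.7% with an intensity trend, and 1.78% and 12.5% in a test against a fold of 1.1.

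Without an adjustment 4131 probes had p below 0.05. A fit on the 12 arrays with the slide as a replicate block, which takes technical arrays as replicates, called 2590 probes higher and 2753 lower in A, and 25.8% of the probes set at 1. The area under the curve for ranking changed above unchanged tested probes by the size of the limma statistic was 0.962.

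The 20 genes named as the brightest of their class lay near their set values, with few exceptions. They were picked among bright probes already called in the set direction, which favours values near the set ones. At 0.25 the position of the Hph probe was chromosome 3R, 1094003 to 1094062, and that of poe was 2L, 8054491 to 8054550. Tbp, the TATA-box binding protein (2R, 17573751 to 17573810), was set at 0.286, which is -1.81 on the log2 scale, and measured -2.18 ± 0.02. ScsbetaG, a succinyl-CoA synthetase subunit (3L, 5554907 to 5554966), was set at the same 0.286 and measured -0.74 ± 0.01 (adjusted p = 0.000864), which is 2.10-fold from its set value. Cyp6a22, a cytochrome P450, measured -1.35 ± 0.11 and tant, a chromatin-associated protein, -1.48 ± 0.11, both set at 0.4 (-1.32). HisCl1, a histamine-gated chloride channel, measured -0.67 ± 0.15 and Faf2 -0.82 ± 0.05, both set at 0.667 (-0.58). Crtc, a CREB coactivator, measured 0.69 ± 0.05 (rounded from 0.685) and Agpat2, an acyltransferase, 0.85 ± 0.08, both set at 1.5 (0.58). Dsor1, the MAP kinase kinase of the Ras pathway, measured 0.72 ± 0.15 and Ama, an immunoglobulin-family protein, 0.68 ± 0.05, both set at 1.7 (0.77).

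Rab4, a small GTPase of endosomes (2R, 13462101 to 13462160), measured 1.12 ± 0.09 and lbk 1.03 ± 0.11, both set at 2. SMC5, a subunit of a chromosome maintenance complex (3L, 21566542 to 21566601), measured 1.82 ± 0.21 and Rlb1 1.25 ± 0.11, both set at 3 (1.58). The smallest set change was 0.833, where Hexo1, a hexosaminidase, measured -0.29 ± 0.12 and RpL17, a ribosomal protein, -0.29 ± 0.02, against -0.26 set. Hexo1 had adjusted p = 0.0367 and RpL17 adjusted p = 0.0139. Neither held when the test asked for a change beyond 1.1-fold, and Hexo1 was also lost under both other loess fits and without the filter on dim probes.

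With 1 probe per gene, the 5 largest departures from set values were all at dim probes that did not pass the test with 2 preparations, and other probes of 3 of these genes did pass it. Atf3, a bZIP transcription factor set at 0.25, measured 0.04 ± 0.01 at a probe with mean log2 intensity 6.95, while its probes at intensities of 9.47 and 9.96 measured -1.87 ± 0.19 and -1.62 ± 0.13 (adjusted p = 0.000423 and 0.00033). Its 2 other probes, also dim, measured -0.06 ± 0.01 and -0.01 ± 0.03, so 3 of the 5 tested probes of Atf3 stayed near 0. With scanner-processed signals the probe at intensity 6.95 measured 0.27 and was called against the set direction. For koko, also set at 0.25, the dim probe measured -0.17 ± 0.003 and the other probes -1.51 ± 0.17 and -1.53 ± 0.18. Alg3, a mannosyltransferase set at 0.25, measured -0.19 ± 0.07 at its dim probe and -1.52 ± 0.07 at the other. The dim probes of koko and Alg3 (adjusted p = 0.0661 and 0.0687) passed the test with the slide as a replicate block, with normexp at offset 0, with scanner-processed signals and with an intensity trend. Without A1Cy5_B1Cy3 replicate 2 or A2Cy5_B2Cy3 replicate 2 koko passed as well (-0.18 and -0.19), and without A2Cy3_B2Cy5 replicate 2 Alg3 did (-0.20). Fs, the fly follistatin, set at 0.25, measured 0.01 ± 0.04, and Pgd, a pentose phosphate enzyme set at 3.5, measured -0.02 ± 0.02; both genes had a single tested probe in the mixture.

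The second question was how the measured ratio tracked the set ratio. Clones set at 0.25 had a class median of -1.87 ± 0.005, those at 0.286 of -1.74 ± 0.003, those at 0.4 of -1.12 ± 0.06 and those at 0.667 of -0.50 ± 0.01 (log2, SD of n = 2 preparations). Clones set at 0.833, which is -0.26 on the log2 scale, had a class median of only -0.15 ± 0.07. Clones set at 1.5 had 0.56 ± 0.03, those at 1.7 had 0.69 ± 0.06 and those at 2 had 0.94 ± 0.02. Clones set at 3 measured 1.66 ± 0.05 and those at 3.5 measured 1.63 ± 0.08. Classes 3 and 3.5 were the one neighbouring pair out of 10 that did not separate: the mean difference (3.5 minus 3) was -0.04, two-sided permutation p = 0.209. The other 9 pairs had adjusted permutation p of 0.0296 (0.25 against 0.286) or 1.25e-05, which comes from the smallest p that the resamples can give, 1e-05. The order of the class medians was kept in 12 of 12 arrays except for 0.833 against 1, 1.5 against 1.7 and 3 against 3.5, each kept in 9 of 12. In the group A1Cy5_B1Cy3 all of these were out of order: the class at 3 had 1.87 and that at 3.5 was lower by a mean difference of -0.37, and the class at 1.5 had 0.61 and that at 1.7 had 0.54.

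**Figure D1:**
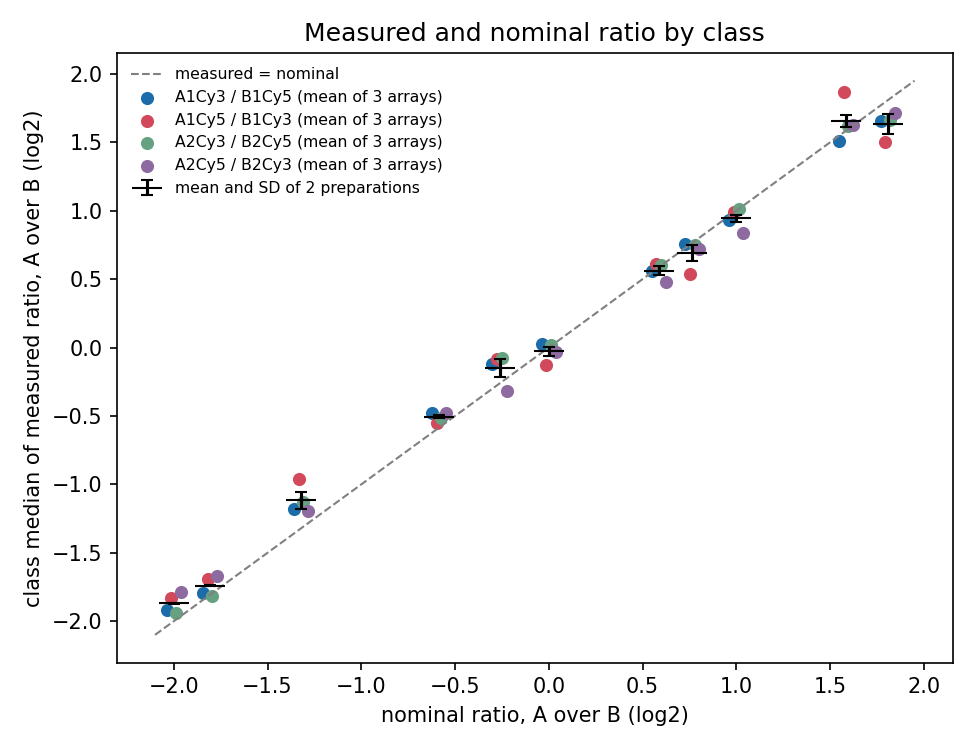
Class medians of the measured log2 ratio of A over B against the nominal log2 ratio, for the 10 classes other than 1 and for 1; coloured points are group means of 3 arrays, set slightly apart along the horizontal axis, black bars are the mean and SD of 2 preparations, and the dashed line marks equality. The classes at 3 and 3.5 overlap (1.66 and 1.63), and A1Cy5_B1Cy3 lies highest at 3 and lowest at 3.5.

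The slope of measured on nominal log2 ratio was 0.884 ± 0.042 (SD, n = 12 arrays), and 0.896 ± 0.013 over the 11 arrays other than A1Cy5_B1Cy3 replicate 2, whose slope was 0.756. In each of the 4 groups the array on slide 2 had the lowest slope, and the mean over the 4 arrays of a slide was 0.902, 0.851 and 0.901 for slides 1, 2 and 3. Slopes averaged 0.871 ± 0.056 in preparation 1 and 0.898 ± 0.018 in preparation 2 (exact permutation p = 0.316, n = 6 each, adjusted p = 0.316), and 0.869 ± 0.056 with A in Cy5 and 0.9003 ± 0.014 with A in Cy3 (exact permutation p = 0.152, adjusted p = 0.303). The 6 arrays of a side carry 2 pairs of labelled samples, so these p-values rest on technical arrays. Within slides 1, 2 and 3 preparation 2 exceeded preparation 1 by 0.0138, 0.059 and 0.009, and A in Cy3 exceeded A in Cy5 by 0.013, 0.0762 and 0.00572, the same sign on all 3 slides. An exact permutation within slides, added after seeing the data, gave p = 0.139 and p = 0.0741 (adjusted p = 0.139 for both). The array A1Cy5_B1Cy3 replicate 2 is on slide 2; without it the exact permutation p over all arrays was 0.654 and 0.286. The slope rose with brightness: in 4 equal bins of mean intensity it was 0.507 ± 0.117, 0.868 ± 0.067, 0.969 ± 0.019 and 1.016 ± 0.025 from dimmest to brightest (n = 12 arrays). Without A1Cy5_B1Cy3 replicate 2, which had 0.151 in the dimmest bin, that bin had 0.539 ± 0.033.

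Among clones set at 0.833, 57 of 229 probes (24.9%, interval 19.4 to 31.0) were called lower in A and 4 higher. Clones set at 0.667 were called at 80.9% (interval 75.7 to 85.4), those at 1.5 at 80.5% (75.2 to 85.0), those at 1.7 at 88.4% (83.5 to 92.2) and those at 2 at 85.2% (80.3 to 89.2). Shares at 3 and 3.5 were 91.6% and 92.8%, and those at 0.4, 0.286 and 0.25 were 87.5%, 91.8% and 88.7%. For the class at 0.833 the group A2Cy5_B2Cy3 had a median of -0.32, and the other 3 groups lay between -0.12 and -0.08. Of the tested changed probes in the dimmest intensity bin 76.2% were called, against 94.4% in the brightest.

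**Figure D2:**
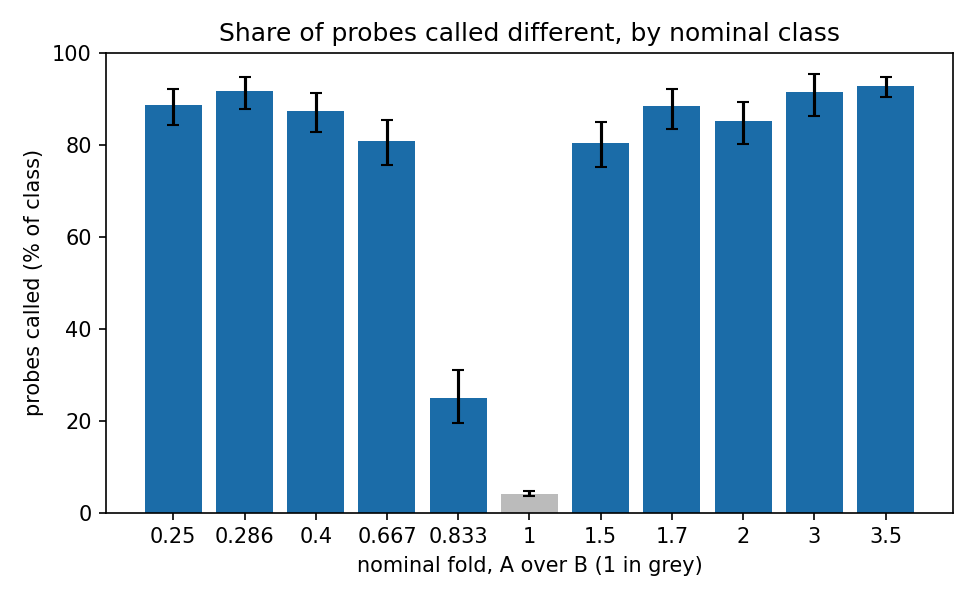
Share of all probes of each nominal class called different in the set direction, or in either direction for the class at 1 (grey), with exact 95% binomial intervals. The class at 0.833 stands at 24.9% and the class at 1 at 4.09%, while every other class lies between 80.5% and 92.8%.

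Gene families were described through lists fixed beforehand, at the brightest probe of each gene in the mixture. Among cytochrome P450 enzymes 34 members were tested; 4 were higher in A and 14 lower (19 called when adjusted over the list alone), and 18 of the 19 members set at a change were called in that direction. The symbol pattern also took in the cyclophilins Cyp40, called lower (-0.57 ± 0.06, set at 0.667), and Cyp1, not tested, which are not P450 enzymes and are among these 19. Cyp12d1-d, set at 0.286, measured -1.82 ± 0.001, Cyp4ac1, set at 0.25, -2.11 ± 0.11, and Cyp6u1, set at 3.5, 1.83 ± 0.24. In the proteasome, the protease complex that degrades ubiquitinated proteins, 22 members were tested, with 6 higher and 5 lower (12 adjusted over the list alone). All 9 members set at a change were called in that direction, among them Prosalpha1 (-2.16 ± 0.05, set at 0.25) and Prosbeta4R2 (1.92 ± 0.09, set at 3.5). Prosbeta2 (-0.26 ± 0.04) and Rpn5 (0.22 ± 0.01) were called although set at 1. Prosalpha7, a dim probe at a log2 intensity of 7.34, was set at 3.5 and measured 0.63 ± 0.02.

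Of 24 tested translation initiation factors 9 were higher and 5 lower (15 adjusted over the list alone), including eIF4H2 (1.94 ± 0.05, set at 3.5) and eIF2gamma (-1.31 ± 0.13, set at 0.4). eIF4E3 (0.86 ± 0.13) and eIF4A (-0.45 ± 0.04) were called although set at 1. Among 17 tested cytosolic ribosomal proteins 5 were higher and 3 lower (9 adjusted over the list alone); RpS23, set at 3.5, measured 1.66 ± 0.02, and RpL11, set at 0.833, measured -0.13 ± 0.04 and was not called. RpS15Aa (0.47 ± 0.01) and RpS15Ab (0.48 ± 0.0001), both set at 1.5, are paralogs. Among 18 tested tRNA synthetase names, of which Aats-glupro and GluProRS are 1 gene, 3 were lower and none higher (3 adjusted over the list alone): CysRS-m (-1.80 ± 0.02, set at 0.25), SerRS (-0.65 ± 0.09) and GlyRS (-0.70 ± 0.14), both set at 0.667. Of 6 tested actins and tubulins 2 were higher and 3 lower (5 adjusted over the list alone); Act42A and Act57B, paralogs set at 0.4 and dim, measured -0.19 ± 0.01 and -0.58 ± 0.09. The histone list had 1 tested member, His2Av, set at 1 and not called (-0.06 ± 0.14; 0 adjusted over the list alone). Of the members set at a change, 12 initiation factors were called in that direction and 3 were not. For ribosomal proteins these counts were 7 and 3, for tRNA synthetases 3 and 1, and for actins and tubulins 4 and 0. None of the called members of these lists changed sign under the 6 other background corrections and normalisations.

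The third question was what the arrays show where no change was set. Of the 216 called probes set at 1, 153 were higher and 63 lower in A, and 44 reached 1.5-fold. The largest among genes with a symbol other than a CG number in the files were fzy, the activator of the anaphase-promoting complex (1.44 ± 0.12; 2L, 16312999 to 16313058), Scsalpha1, another succinyl-CoA synthetase subunit (1.40 ± 0.19; 3L, 3818077 to 3818136), and br, an ecdysone-response transcription factor (1.26 ± 0.34; X, 1555365 to 1555424). unc-119 measured -1.02 ± 0.04 (X, 7182713 to 7182772) and Gclm, a glutamate-cysteine ligase subunit, 0.96 ± 0.05 (3R, 18511059 to 18511118). Their adjusted p ran from 0.000398 for fzy to 0.0044 for br. Probes of one gene did not always go together: among 4 probes of br a pair measured 1.26 and 1.18 and the other pair -0.21 and -0.20. Another probe of fzy measured 0.01 ± 0.08, but it is too dim (log2 intensity 7.04) to decide on a disagreement. A second probe of Scsalpha1 measured 1.05 ± 0.44.

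Probes listed at 0 gave signal in part. In A1Cy3_B1Cy5, A2Cy3_B2Cy5 and A2Cy5_B2Cy3 the share well above background was 14.3% ± 2.1, 14.7% ± 3.4 and 13.1% ± 0.8 (SD, n = 3 arrays). In A1Cy5_B1Cy3 it was 37.2% ± 43.5, and 12.1% without replicate 2, which had 87.5%. Of the 23310 probes listed at 0, 2845 (12.2%) were bright enough to test, mostly near the floor: their median log2 intensity was 7.14, against 13.89 for tested mixture probes. The test called 410 of them, 212 higher and 198 lower in A, and 130 reached 1.5-fold. The brightest were RpS5b, a ribosomal protein (log2 intensity 17.20), Dhod, a pyrimidine synthesis enzyme (16.88), and Noa36 (16.23). RpS5b measured -0.06 ± 0.07, Dhod -0.08 ± 0.05 and Noa36 -0.20 ± 0.05; Noa36 had adjusted p = 0.0489, and the others 0.431 and 0.305. The call of Noa36 was lost under 12 alternatives, with adjusted p from 0.0502 to 0.387; they include leaving out A1Cy3_B1Cy5 replicate 2, A1Cy5_B1Cy3 replicate 1 or 3, or A2Cy5_B2Cy3 replicate 1 (adjusted p = 0.0502, 0.0682, 0.0614 and 0.0528). The labels do not say whether a listed 0 means that a clone was absent from the mixture. The 172 chemoreceptor gene names on the array, which encode odorant, gustatory and ionotropic receptors, have no probe with a listed ratio above 0, and 27 of them had a probe bright enough to test.

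**Figure D3:**
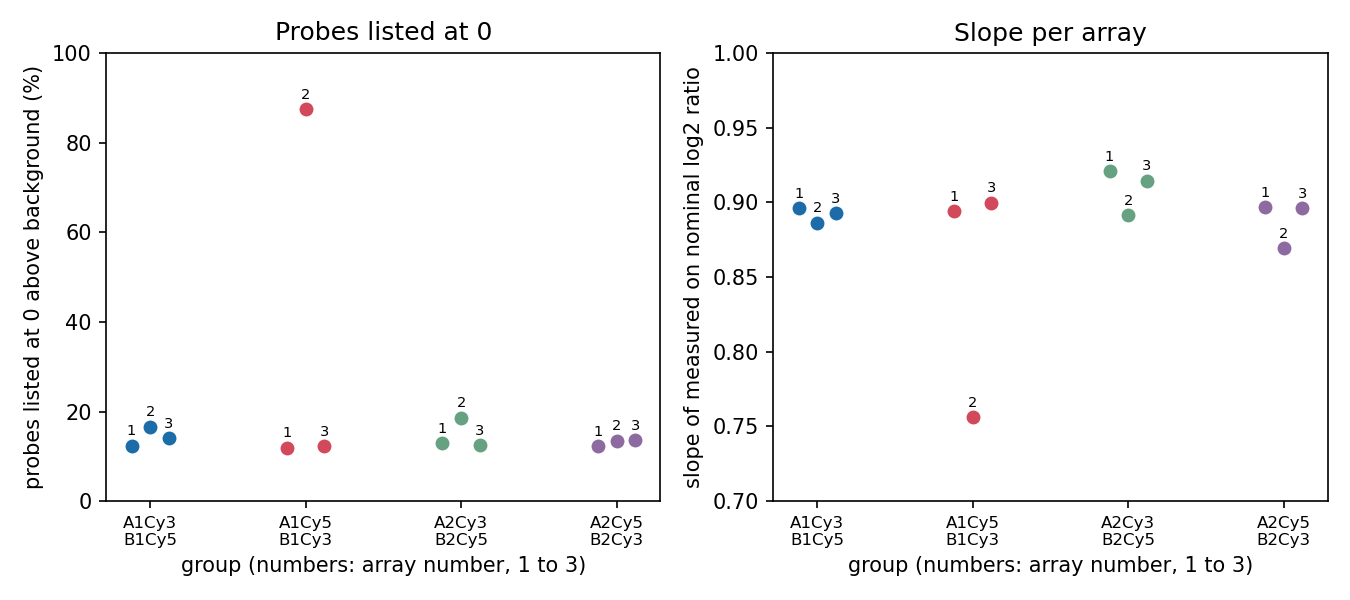
Left, share of the 23310 probes listed at 0 that were well above background on each of the 12 arrays; right, slope of measured on nominal log2 ratio on the same arrays (vertical axis from 0.7 to 1). Points are single arrays marked with their number within the group; A1Cy5_B1Cy3 replicate 2 stands at 87.5% and 0.756, the other 11 arrays between 11.9% and 18.6%.

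The design also asks whether dye or preparation moved the ratios. Bright probes differed in their dye effect: Syx16 had a dye effect of 1.09 ± 0.07 (log2 Cy5 over Cy3), Crtc 0.78 ± 0.02, Rab4 0.77 ± 0.08 and RpL17 -0.02 ± 0.03. With 2 preparations limma called 0 probes for a dye effect (adjusted p = 0.116 for Syx16), while 2211 probes had an unadjusted p below 0.05. At the same n of 2 preparations the count was 357 with normexp at offset 0, 119 with scanner-processed signals and 99 with median centring. On the 12 arrays taken as if independent the same test called 4501, and with the slide as a replicate block 4110. Across tested mixture probes the dye effects of the 2 preparations correlated with r = 0.584 and rho = 0.497; probes are not independent replicates. The median size of a dye effect was 0.11 and the 90th percentile 0.34.

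Between preparations 5 probes differed in the ratio of A over B, all lower in preparation 1: ClpP, a mitochondrial protease (preparation 1 minus 2, -0.36), Mob4 (-0.33), cl (-0.27), Pax, the fly paxillin (-0.41), and CG2681 (-0.43), with adjusted p from 0.0155 to 0.0353. These genes fall outside the naming rule and were named after their values were seen. Unadjusted, 1925 probes had p below 0.05. With the slide as a replicate block 0 were called, and 0 were called when any of 6 single arrays was left out: A1Cy3_B1Cy5 replicate 2 or 3, A1Cy5_B1Cy3 replicate 1, A2Cy3_B2Cy5 replicate 1 or 2, or A2Cy5_B2Cy3 replicate 2. The other arrays left out gave counts from 1 to 7, the highest without A1Cy5_B1Cy3 replicate 2.

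The spread had its largest part between dye orientations. Over tested probes the median SD was 0.10 between arrays of a group (pooled over groups), 0.17 between the 2 orientations of a preparation and 0.06 between preparation means (log2). By group, the median SD between arrays was 0.06 for A1Cy3_B1Cy5 and for A2Cy3_B2Cy5, 0.07 for A2Cy5_B2Cy3 and 0.11 for A1Cy5_B1Cy3, with a mean over groups of 0.07. The last group holds the array with raised signal, replicate 2, which all SDs and correlations of this paragraph include. Leaving that array out lowered the mean over groups from 0.074 to 0.059. Over probes set at 1, the 2 groups with A in Cy3 correlated at r = 0.926 and the 2 groups with A in Cy5 at r = 0.342, while A1Cy3_B1Cy5 against A2Cy5_B2Cy3 had r = -0.23. Over all tested mixture probes the 6 correlations between groups ran from 0.816 to 0.992.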

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

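The comparison of the dye effect between preparations, with its values without 1 array and with the slide as a block, was chosen after the data were seen, and the splits of the arrays were planned.

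The ratio of A over B differed between preparations at 5 probes, by a test of the difference on the 12 arrays. Of 100 splits of the arrays that keep the dye orientations balanced, 2 gave at least as many probes, the real one included. This does not exclude chance: splits that break up the groups move the differences between labelled samples into the residual, which lowers their counts. The real split gave 5 and the highest of the others 1601 probes, several times the real count, and it sets A1Cy3_B1Cy5 with A2Cy5_B2Cy3 against the other pair of groups. That split contrasts the dye effect of preparation 1 with that of preparation 2, so its count points to a structure of the arrays by labelled sample. The next highest split gave 0. With the slide as a block the preparation difference itself was called at 0 probes by limma (5 without the block, 1925 unadjusted).

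By a limma interaction term on the 12 arrays, the dye effect differed between preparations at 1601 probes (3331 at an unadjusted p below 0.05). The count was 2336 without A1Cy5_B1Cy3 replicate 2 and 553 with the slide as a block. Each group is 1 pair of labelled samples, A and B, hybridised to 3 arrays. This count therefore sets differences between labelled pairs against technical spread only, and it does not show an effect beyond these samples. Of the 1601 probes, 789 were set at 1, 508 were set at a change and 183 were listed at 0. The dye effect averaged over both preparations was called at 4501 probes on the 12 arrays. An effect in 1 preparation alone can pass that test. Only 1 of 100 splits that keep the preparations balanced, the real one, gave as many, and the highest of the others gave 15. These splits break up the dye groups in the same way, so they do not exclude chance either; with preparations as the unit limma called 0 dye effects (2211 unadjusted).

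Signal outside the comparisons came from the E1A control spots, probes for a commercial spike-in RNA. All 10 E1A controls were brighter than the median of the negative control spots. The slope that the scanner software gives for these controls averaged 0.842 over 12 arrays, with an SD of 0.062. It was 0.858 ± 0.025 over the 11 arrays other than A1Cy5_B1Cy3 replicate 2, which had 0.661.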

How the results depend on the processing

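No named gene that was called changed direction under the alternatives run; Pgd, RpS5b and Fs, not called, changed sign in 3 values; 17 calls of named genes were lost under single alternatives, at Noa36, Hexo1 and RpL17, and 24 values of koko, Alg3, Atf3, RpS5b and Dhod passed the threshold under an alternative. Depth is set by signal over background: 193 probes set at a change were too dim to test. The cause was not tested for any shift below.

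Shares called are given as probes set at a change, probes set at 1, and calls at 1 or listed at 0 among all calls (82.9%, 4.09% and 19.5% as reported). Normexp with offset 0 gave 85.5%, 7.77% and 30.3%, with 357 dye effects and 0 preparation differences. Without background correction the last 2 shares were 4.77% and 21.6%. Scanner-processed signals gave 6.76% and 33.8%, a slope of 0.950 and 119 dye effects. Median centring gave 3.45% and 17.6%, 99 dye effects, 0 preparation differences and an array SD of 0.39. Loess on probes set at 1 gave 5.95% and 23.4%, with 8 preparation differences; loess on mixture probes gave 6.25% and 24.0%. With no filter on dim probes the values were 5.17%, 22.5% and a slope of 0.824. Requiring both channels above background on all arrays gave 5.10% of probes set at 1. In the brighter part of the probes (above the median intensity) the slope was 0.996. The robust array SD (scaled MAD) was 0.045. Class medians left the SD of 2 preparations in 50 values and stayed within it in 170. Median centring moved all 11 of them, with the median log2 ratio, nominal fold 0.25, at -1.95.

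On 12 arrays as if independent, 3022 probes were lower in A, with shares of 88.7%, 30.8% and 49.5% and 4501 dye effects. With the preparation as a random block these were 2495 probes, 87.8%, 21.3% and 42.5%. With the slide as a replicate block they were 2753 probes, 88.3%, 25.8% and 46.5%, with 4110 dye effects and 0 preparation differences. The block also brought koko and Alg3 past the threshold, with ratios of -0.17 and -0.19. An intensity trend gave 2058 probes lower, 86.3%, 10.9% and 37.7%. A test against a fold of 1.1 gave 79.0%, 1.78% and 12.5%. Preparation 1 alone gave 3163 lower, 85.9%, 36.1%, 49.2% and an area of 0.912, and preparation 2 alone 3298 higher, 2825 lower, 90.3%, 35.2% and 50.9%.

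Chosen after seeing the data, slide 1 alone gave 6.38% and 23.3% for the last 2 shares; slide 2 gave 73.2%, 1.00% and 8.40%; slide 3 gave 84.3%, 7.48% and 25.6%. The numbers called on slides 1, 2 and 3 alone were 1992, 1385 and 2066 higher and 1428, 1056 and 1513 lower in A. A slide effect in the dye direction, also added then, left 4288 dye effects and 2 preparation differences. Of the probes listed at 0, 9.71% in A2Cy3_B2Cy5 and 6.17% in A2Cy5_B2Cy3 lay above the 99th percentile of negative controls.

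Leaving out 1 array at a time, preparation differences ranged from 0 to 7, the share of probes set at 1 from 2.99% to 5.97%, and calls at 1 or listed at 0 from 16.5% to 23.1%; for these shares the lowest value was without A1Cy5_B1Cy3 replicate 3 and the highest without its replicate 2. Without that replicate 2, 3415 probes were called and 3190 of the 3218 calls remained. Other counts and shares stayed within 1.5 times their count or within their spread.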

Other observations

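The tests of other probes of the same gene (unusual binding and another clone ratio), of the raised array and of brightness in the class order, the comparison of 2 probes per gene, the values per gene and the shifts of all classes were chosen only after the result was seen. The design names no biological difference between A and B, so no biological explanation was tested.

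Array A1Cy5_B1Cy3 replicate 2 had a median signal of 629 in Cy5 and 230 in Cy3 at probes listed at 0, against at most 73.0 and 58.0 on the other 11 arrays, while its local background in Cy5 was 61 and the highest of the others 62. A stain or bubble is argued against: the lowest of 32 block medians over the array was 564 in Cy5. Stronger binding of the mixture's own RNA to unmatched probes, in the same order of probes as elsewhere, is argued against too. The ranks of this array at these probes followed those of the other arrays with rho = 0.040 in Cy5, where each of the others reached between 0.746 and 0.882. In Cy3 the array had rho = 0.214. On the other arrays these probes lie near background, so the test cannot decide on binding in another order. RNA from fly cells in the labelled material shared by the group is argued against. Replicates 1 and 3 of the group had Cy5 medians of 69.7 and 68.2 at probes listed at 0. Such RNA on this array alone stays open. Its ribosomal protein probes listed at 0 were 1.29 times as bright as chemoreceptor probes listed at 0, between the bounds for and against it. The medians were 622 over 162 probes and 482 over 199, and the other arrays had ratios from 0.930 to 0.981. Negative controls rose as well, to a median of 177 in Cy5 against at most 66.1 elsewhere, and the 3 other arrays of the slide had at most 12191 probes above background.

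Of the 44 probes set at 1 but called at 1.5-fold or more, 25 have another tested probe of the same gene set at 1. Normalisation is argued against, since at least 42 of the 44 stayed at 1.5-fold or more in the same direction under 6 other settings. Unusual binding at single probes stays open, as 72.2% of 36 comparisons with another probe lay on the same side; these hold 31 distinct other probes, and pairs in which both probes are among the 44 count in both directions. With 1 value per gene, the median of the other probes lay on the same side as the brightest of the 44 in 11 of 14 genes (78.6%, interval 49.2 to 95.3). That a clone was present at another ratio than listed is a candidate explanation for part of the set: over the 36 comparisons the median was 1.65-fold in the direction of the first probe, and over the 14 genes 1.646-fold, with 9 genes at 1.5-fold or more. Ratios were alike at both probes for CG1662 (1.36 and 1.55), Hap40 (0.81 and 0.74), HmgD (0.76 and 0.72) and alphaTub84B (0.74 and 0.77), whereas fzy and Usp10 had a second probe at 0.01 and -0.005 and qvr (0.70) had 5 others between -0.12 and -0.005. The second probe of fzy counts as the same side above. It is dim (log2 intensity 7.04), and dim probes of Atf3 and Pgd set at a change also measured near 0. That probe therefore cannot decide whether the probes of fzy disagree. Of 4 probes of br, a pair measured -0.21 and -0.20. Sequence shared with a clone set at another ratio would give the same picture and was not tested.

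In A1Cy5_B1Cy3 the class at 3.5 measured below the class at 3, by -0.37 as the mean of its arrays, and the other 3 groups had differences from 0.05 to 0.15. The array with raised signal is argued against as the cause, because the difference in the other arrays of the group was -0.28 or lower. Brightness is argued against, because the difference in this group was -0.16 within the brighter probes of these classes and -0.35 within the dimmer. Opposite shifts of both classes against A2Cy5_B2Cy3 were not seen, since 57.8% of probes at 3.5 moved down where over 80% had been predicted. That bound asked for both classes to move. In the class at 3, 80.6% of probes moved up by a median of 0.27. The classes at 0.4, 0.833, 1.5 and 2 were also higher than in A2Cy5_B2Cy3. Their median differences were 0.27, 0.30, 0.26 and 0.28, and those of the remaining classes lay between -0.07 and 0.01. With 1 reference group this cannot tell which group moved. At 0.833 A2Cy5_B2Cy3 stood apart (-0.32, the others -0.12 to -0.08). At 3 A1Cy5_B1Cy3 stood apart (1.87, the others 1.51 to 1.63). A shift of the class at 3 alone in A1Cy5_B1Cy3 therefore stays open. Why these classes differed between the groups was not tested.

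Across the 712 genes with exactly 2 tested probes set at 1, the ratios of the 2 probes correlated with r = 0.632, where 1000 random pairings reached at most 0.161; genes are not independent replicates here.

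Set against A2Cy5_B2Cy3, and relative to probes set at 1, the ratios in A1Cy5_B1Cy3 (replicates 1 and 3 of each) were higher by a median of 0.27 in the class at 0.4, 0.30 at 0.833, 0.26 at 1.5, 0.28 at 2 and 0.27 at 3, with up to 86.2% of the probes of a class above (at 0.833), and 80.6% at 3. Medians in the other 5 classes lay between -0.07 and 0.01.

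The probes under the text code MC gave 220 calls among 612 tested (35.9%, interval 32.1 to 39.9), and the 16 under MF gave 10.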
